A study of Mus musculus with 466 samples.

How the data were processed

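Gene expression was measured on Affymetrix arrays with biotin-labelled total RNA from 6 tissues of male C57BL/6J mice, and 466 arrays from 80 animals were used. The deposited table holds 1 intensity per probe set and array, and the values are linear. All values were above 0, and the mean over the probe sets of an array lay between 0.962 and 0.999. How the authors summarised, normalised or filtered the intensity values is not given in the sources used here. The value distributions nearly coincided within a tissue and differed between tissues, so no value of one tissue was set against another except for tissue marker genes. The number of arrays limits the precision.

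Of 32640 probe sets, 25508 carried 1 gene symbol and 7132 carried none. The symbols were matched to a current gene table of assembly GRCm38.p6, used for names only, which updated 2830 older names and gave 16643 gene symbols, of which 16601 were in that table. The log2 of each deposited intensity was taken without an offset. Where a gene had more than 1 probe set (5825 genes), the probe set with the highest mean in the tissue stood for it. Genes whose mean lay above the percentile 25 of all probe sets' means were tested, which left from 13179 genes in hypothalamus to 13633 in the depot labelled perirenal.

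Each tissue was fitted on its own with limma 3.58.1 in R 4.3.3 (trend and robust options), with the day of restriction as a factor and the letter that opens the animal ID as an additive term. The letter was included because day 1 holds only J animals and day 60 only N animals, and its meaning is not given in the labels. Each day was set against day 0, day 42 against day 3 and letter N against letter J, and a moderated F test covered all days. A second fit of the days that hold both letters tested whether the day 42 effect differed between letters. A further fit of each pair of depots tested whether the day 42 effect differed from that in the depot labelled subcutaneous. P-values were adjusted by the method of Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. All tests were two-sided.

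Gene lists of pathways and cell types were written before the data were examined. For each list the members called over all genes and those called when adjusted over the list alone were counted. The lists were also tested with camera, once with a preset correlation of 0.01 and once with the estimated correlation between genes, with adjustment over the lists of that tissue and day. On simulated data camera with the preset correlation called 49 of 140 lists that held no change. With the estimated correlation it called 0 of these 140, and 5 of 6 shifted lists. Short lists, such as that of the erythrocyte markers, were left out of this simulation, so it does not cover them. On the real data 100 of 338 list tests passed with the preset correlation and 6 with the estimated one, so list results are given as counts of members with the p from the estimated correlation.

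The genes named were set by a rule written beforehand. For each tissue the rule took, at day 42, the 7 higher and 7 lower called genes with the largest change, and at day 3 the 4 higher and 4 lower, among those with the same direction in J and in N animals alone. It added up to 4 called members of each list discussed, those with the smallest adjusted p, and a set of key genes reported whatever they showed. Genes outside this rule are named as chosen after their values were seen. The count of mice on the side of a change refers to mice with a letter, each set against the day 0 mean of its own letter.

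The scripts were tested on simulated changes in the real arrays' structure before use. At day 42 a shift of 0.25 on the log2 scale was recovered for 95.5% of shifted genes in hypothalamus, 86.6% in liver, and from 64.2% to 82.1% in the 4 depots. A shift of 1 was recovered for 93.9% to 100% of genes in the 6 tissues. Many genes were shifted at once, which eases the adjustment over the genes tested. The recovery may therefore be lower where few genes change, as in hypothalamus, where 0 genes were called at day 42. Genes without a shift were also called, 1 in hypothalamus, 6 in liver, and 32, 23, 0 and 8 in the depots labelled subcutaneous, mesenteric, perirenal and perigonadal, and for the depots labelled subcutaneous and mesenteric these false calls made up more than 0.05 of all calls. For the difference between depots a shift of 0.25 was recovered for 40.3% to 42.4% of genes and a shift of 0.5 for 73.1% to 83.6%. There were 0 false calls for the depots labelled mesenteric and perigonadal and 12 for that labelled perirenal, there also more than 0.05 of all calls.

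Arrays of one animal in several tissues carry the same animal ID, so the arrays of the depots compared are paired by animal. The main fit of the depots did not use this pairing, and within-animal differences were fitted as an alternative. The residuals of 2 tissues of the same animal had a median correlation from 0.014 to 0.151, against -0.0052 to 0.0115 for different animals. No pair of arrays within a tissue was identical. The alternatives tried were no letter term, J or N animals alone, quantile normalization, no filter on low values, the median over a gene's probe sets, leaving out each day 1 mouse in turn, within-animal differences between depots, and the estimated correlation for lists. After the data were seen, covariates for marker scores of other tissues and the omission of arrays high in such scores were added. These scores were the mean log2 values, centred per gene, of marker lists of other tissues or cell types, and an array counted as high when it exceeded the tissue's median by 3 median absolute deviations on any of them. Each count was compared with 100 random splits of the same animals, drawn with fixed seeds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets without a symbol were left out of the gene counts and tested separately, and no column of the table was left out.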

Results

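Transcript levels were measured in 6 tissues of 80 obese male C57BL/6J mice that had been fed a restricted diet for 0 to 60 days. The labels name hypothalamus (74 arrays), liver (80), and the subcutaneous (78), mesenteric (79), perirenal (80) and perigonadal (75) adipose depots. Liver held 12 mice at day 0, 5 at day 1, 11 at day 3, 12 at day 7, 10 at day 14, 12 at day 21, 12 at day 42 and 6 at day 60, and the other tissues held up to 2 fewer mice per day. The series text lists sampling days up to 42, and its title and the labels include day 60. Animal IDs open with the letter J or N, except for 1 day 3 mouse without a letter. Day 1 holds J mice alone and day 60 N mice alone. The time course asks how expression in each tissue moved away from day 0 during caloric restriction. No unrestricted mice were sampled after day 0, so a change with age is part of each contrast. Changes are log2 fold changes ± the standard error of the limma fit, with adjusted p-values over the genes tested in that tissue.

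Marker genes separated the tissues. The median intensity of Alb, the albumin gene, was 35.7 in liver and 0.0595 in hypothalamus. Snap25, a synaptic protein gene, had a median of 17.5 in hypothalamus and 0.0188 in liver. Adipoq, the adiponectin gene, had medians of 18.7, 18.3, 18.9 and 19.1 in the depots labelled subcutaneous, mesenteric, perirenal and perigonadal, against 0.0144 in hypothalamus. The mesothelial genes Wt1 and Upk3b, which mark visceral fat, did not follow the depot names. The median of Wt1 was 0.752 in the depot labelled subcutaneous, 0.506 in that labelled mesenteric, 0.255 in that labelled perirenal and 0.0202 in that labelled perigonadal. Upk3b had medians of 4.24, 2.66, 1.66 and 0.0814 in the same order.

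Further markers were chosen after their values were seen. Fabp2, an intestinal fatty acid binding protein gene, had a median of 11.5 in the depot labelled subcutaneous and 0.0286 in that labelled mesenteric, and it was also high in liver (12.5). The epididymal genes Adam7 and Lcn5 had medians of 0.258 and 0.328 in the depot labelled mesenteric, against 0.0227 and 0.0761 in that labelled perigonadal. Tbx15, a transcription factor of subcutaneous fat, had a median of 0.520 in the depot labelled perigonadal and 0.0543 in that labelled subcutaneous. Ckm, a muscle creatine kinase gene, was also highest in the depot labelled perigonadal, at 1.16. Ucp1, the uncoupling protein of brown fat, had a median of 11.8 in the depot labelled perirenal. Depots are therefore named below as labelled.

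**Figure D1:**
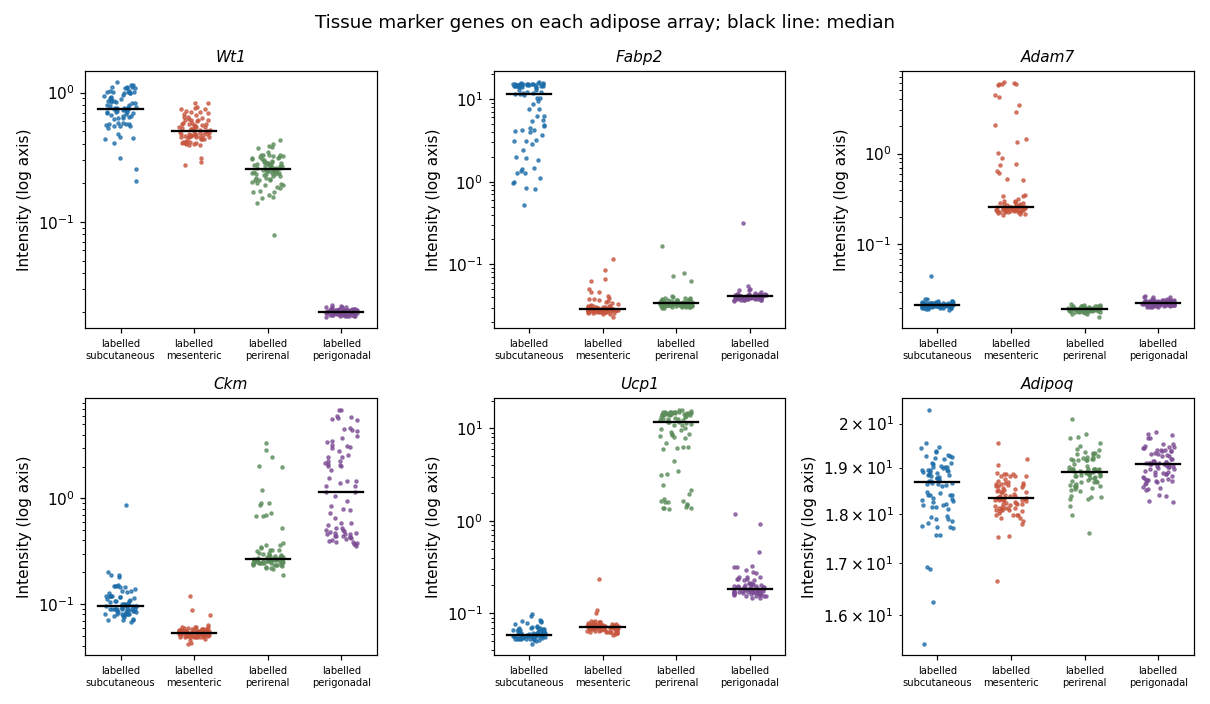
Intensity of depot marker genes on a log axis, with a point per array, in the 4 depots as labelled. Wt1 is lowest in the arrays labelled perigonadal, with a median of 0.0202, and Ucp1 is highest in the arrays labelled perirenal, with a median of 11.8.

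More genes were called at day 42 than at day 3 in 5 of the 6 tissues. At day 60 fewer were called than at day 42 in liver and in the depots labelled mesenteric, perirenal and perigonadal. Day 60 held 6 mice, all of letter N, against 10 to 12 mice at day 42 in these tissues. Day 60 was not tested against day 42, so the lower counts do not show that changes receded. In liver 492 genes had changed at day 1, 553 at day 3, 1652 at day 14, 1211 at day 21, 2885 at day 42 and 2711 at day 60. The counts at days 1, 3, 14, 42 and 60 in the depot labelled mesenteric were 6, 73, 587, 4338 and 3524. Those in the depot labelled perigonadal were 48, 207, 1804, 3615 and 2925. Those in that labelled perirenal were 5, 3, 80, 2995 and 2744. For the depot labelled subcutaneous limma called 0 genes at day 1 (348 at an unadjusted p under 0.05) and 0 at day 3 (283 unadjusted), then 9 at day 14, 542 at day 42 and 1308 at day 60. With marker scores of other tissues as covariates the day 1 count in the depot labelled perigonadal was 104, the day 14 counts were 323 in the depot labelled mesenteric, 32 in that labelled perirenal and 56 in that labelled subcutaneous, and the day 60 counts were 1945 in that labelled mesenteric and 1579 in that labelled perigonadal. Without arrays high in these scores the day 1 counts in the depots labelled subcutaneous, mesenteric, perirenal and perigonadal were 3, 0, 3 and 13, and the day 14 counts were 928 in liver, 239 in the depot labelled mesenteric, 5 in that labelled perirenal and 2 in that labelled subcutaneous. The 5 genes higher at day 1 in the depot labelled perirenal, named after their values were seen, were Aqp11, Asb9, BC049762, Morn5 and Mtfr1. The day 1 groups held 5 mice, and leaving out single mice gave 140 to 703 genes in liver, with 271 without J15, 180 without J20 and 140 without J60. The same omission in the depot labelled perigonadal gave 3 to 83 genes, with 30 without J7, 14 without J15, 22 without J20, 3 without J60 and 83 without J80. For that labelled perirenal it gave 0 to 58, with 0 without J7, 8 without J15, 58 without J20, 13 without J60 and 18 without J80.

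**Figure D2:**
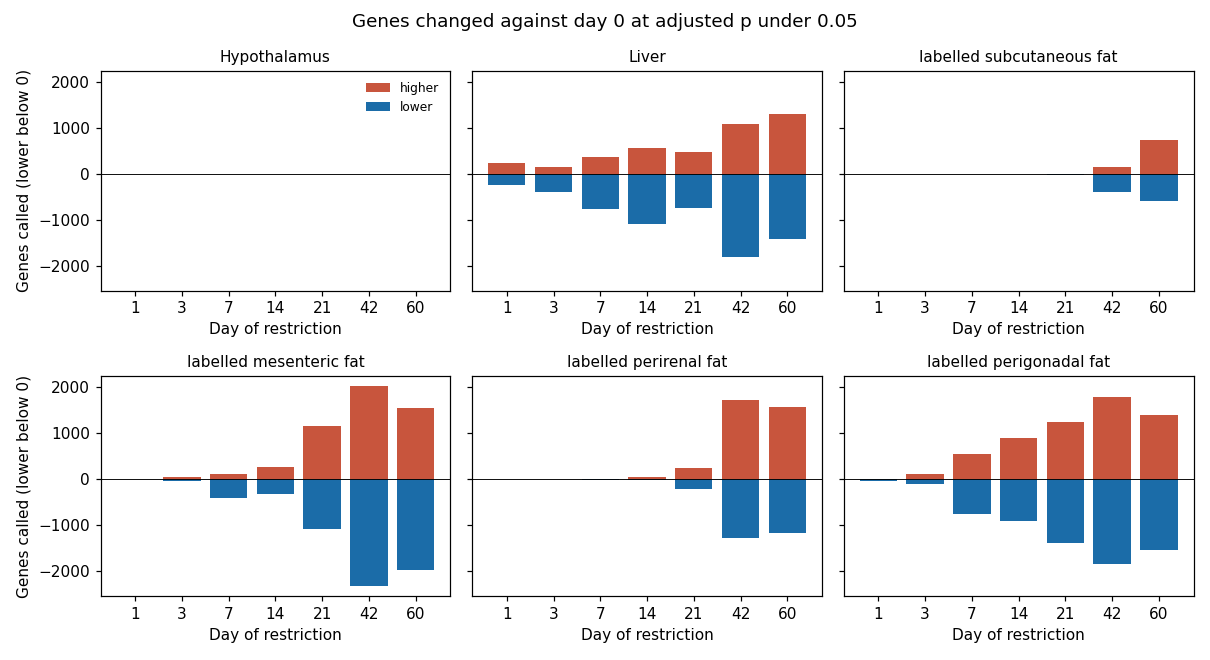
Number of genes with an adjusted p under 0.05 against day 0 at each day of restriction, per tissue as labelled, higher and lower genes apart. The count in liver is 492 at day 1 and 2885 at day 42, and in hypothalamus it is 0 at day 42.

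In hypothalamus none of the key appetite genes passed the test over all genes at day 42. Agrp, which encodes a peptide that stimulates feeding, was at 0.252 ± 0.0395 (SD, n = 10) at day 0 and at 0.426 ± 0.231 (SD, n = 12) at day 42. Its log2 change of 0.63 ± 0.18 had an adjusted p of 0.566, with 10 of 12 mice higher. Npy, the gene of another feeding-stimulating peptide, differed by 0.32 ± 0.09 (adjusted p = 0.51, 11 of 12 mice higher). Pomc, the precursor of melanocortins that curb feeding, differed by -0.23 ± 0.13 (adjusted p = 0.87, 9 of 12 mice lower). The day 42 differences of Cartpt, Lepr, Hcrt, Pmch, Crh, Trh and Socs3 lay between -0.09 and 0.31, and none passed the test. Of 13 genes of orexigenic signals, 0 were called over all genes and 2 when adjusted over the list alone at day 42 (adjusted p = 0.284 with an estimated correlation).

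At day 3 the members of 3 lists lay lower in hypothalamus as sets, although 0 single members were called over all genes. These were the circadian clock (18 genes, median -0.03, adjusted p = 0.0227 with an estimated correlation), immediate early genes that follow neuronal activity (19 genes, median -0.10, adjusted p = 0.0414) and markers of thalamus, cortex and striatum (12 genes, median -0.17, adjusted p = 0.0227). Adjusted over the list alone, 0 clock genes, 2 immediate early genes and 0 of the regional markers were lower. The last list marks neighbouring brain, which moved with the other sets. Across 13179 genes limma called 0 at day 3 (1103 at an unadjusted p under 0.05) and 0 at day 42 (733 unadjusted). At day 60 it called 2, and named after their values were seen these were the metallothionein gene Mt2, which fell by 0.16, and Dusp19, which rose by 0.18. Day 42 against day 3 gave 1 gene, Alas2, the erythroid enzyme of haem synthesis.

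In liver at day 3 several clock genes had changed. Arntl, the BMAL1 gene of the clock, rose by 0.95 ± 0.17 (n = 11 against 12, adjusted p = 0.000286, 10 of 10 mice with a letter). Nr1d1, which represses Arntl, fell by 0.70 ± 0.14, and the clock output gene Dbp fell by 0.69 ± 0.16, each in 10 of 10 mice. Of 17 clock genes 4 rose and 6 fell over all genes, and 4 and 8 adjusted over the list alone (adjusted p = 0.397 with an estimated correlation). Cry1 and Nfil3 rose by 0.44 ± 0.10 and 0.39 ± 0.08, and Ciart, a clock repressor, fell by 0.47 ± 0.13.

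Of 24 genes of fatty acid and triglyceride synthesis 6 fell and 0 rose in liver at day 3, with 14 lower adjusted over the list alone (adjusted p = 0.353 with an estimated correlation). Fasn, the fatty acid synthase gene, fell by 0.40 ± 0.10 (adjusted p = 0.0115, 10 of 10 mice), and Gpam, which starts glycerolipid synthesis, fell by 0.13 ± 0.04. Of 18 cholesterol genes 3 fell, which were Stard4, Sc5d and Nsdhl, and also 3 adjusted over the list alone (adjusted p = 0.507 with an estimated correlation). Of 18 acute phase genes 5 rose and 0 fell, with 11 and 1 adjusted over the list alone (adjusted p = 0.226 with an estimated correlation). Among them were Lcn2, the lipocalin 2 gene (0.72 ± 0.20), and Orm2, an orosomucoid gene (0.59 ± 0.13). Apol11b and Clpx, a mitochondrial protease subunit gene, rose by 0.67 ± 0.15 and 0.61 ± 0.15, and Rgs16, a regulator of G protein signalling, fell by 0.90 ± 0.25. In all, 160 of 13536 genes rose and 393 fell. The count of 553 was 1 in J mice alone and 76 in N mice alone.

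At day 42 several genes known from lipid droplets and fat cells fell in liver, where no list of lipid storage genes was tested. Cidec and Cidea, which coat lipid droplets, fell by 1.21 ± 0.16 (adjusted p = 2.67e-08) and 0.96 ± 0.22, each in 12 of 12 mice (n = 12 against 12). Mogat1, an enzyme of triglyceride assembly, fell by 0.90 ± 0.12, and Cfd, the adipsin gene, fell by 1.32 ± 0.25. Pparg, a lipid storage regulator, fell by 0.40 ± 0.09. Of 10 adipocyte genes measured in liver 4 fell and 0 rose, with 4 and 1 adjusted over the list alone (adjusted p = 0.674 with an estimated correlation). Mt2, a metal-binding metallothionein gene, fell by 1.21 ± 0.22, Themis, a T cell gene, by 1.31 ± 0.17 and Zbed5 by 0.93 ± 0.09. Genes higher at day 42 were Pcp4l1 (0.74 ± 0.09), the transferrin receptor gene Tfrc (0.69 ± 0.10), the steroid dehydrogenase gene Hsd3b1 (0.69 ± 0.26), the lipoprotein lipase regulator gene Angptl8 (0.59 ± 0.13), the vasopressin receptor gene Avpr1a (0.58 ± 0.08), Acnat2 (0.55 ± 0.11) and Arntl (0.64 ± 0.16).

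Cell cycle genes were lower in liver at day 42, with 14 of 20 lower and 0 higher, and 15 lower adjusted over the list alone (adjusted p = 0.123 with an estimated correlation). Ube2c, a mitotic ubiquitin-conjugating enzyme gene, fell by 0.42 ± 0.05, and Prc1, a cytokinesis gene, by 0.29 ± 0.05, each in 12 of 12 mice. Of 3 erythrocyte markers 2 also fell, Alas2 by 0.45 ± 0.10 and Slc4a1 by 0.20 ± 0.06, each in 11 of 12 mice (adjusted over the list alone also 2, adjusted p = 0.433 with an estimated correlation). With marker scores of muscle and red blood cells as covariates 7 of the 20 cell cycle genes were lower. Fatty acid oxidation and ketogenesis had 12 of 24 genes lower, and 13 adjusted over the list alone (adjusted p = 0.433 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, fell by 0.28 ± 0.04, Ppara, the nuclear receptor of the fasting response, by 0.20 ± 0.03, and the hormone gene Fgf21 by 0.29 ± 0.10. Of 22 genes of the unfolded protein response 11 rose and 1 fell, with 13 and 2 adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). The chaperone genes Hspa5 and Hyou1 rose by 0.17 ± 0.04 and 0.49 ± 0.10, and Trib3 fell by 0.46 ± 0.07. Of 16 heat shock genes 7 rose and 0 fell, with 10 and 1 adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). Hsp90aa1 rose by 0.29 ± 0.04 in 12 of 12 mice.

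Cholesterol synthesis genes in liver at day 42 counted 5 of 18 higher and 0 lower, and 7 higher adjusted over the list alone (adjusted p = 0.674 with an estimated correlation). Sqle and Lss, enzymes of sterol synthesis, rose by 0.39 ± 0.09 and 0.30 ± 0.08. Interferon response genes counted 1 higher and 5 lower of 19, and 1 and 8 adjusted over the list alone (adjusted p = 0.813 with an estimated correlation), with Rsad2 lower by -0.33 ± 0.06. Srebf1, the lipogenic transcription factor gene, rose by 0.17 ± 0.06 (adjusted p = 0.0374, 10 of 12 mice). The difference of Fasn was 0.18 ± 0.10 at day 42 (adjusted p = 0.18, 8 of 12 mice higher), and at day 60 it rose by 0.54. Pck1, G6pc, Scd1 and Igfbp1 differed by -0.13, -0.01, -0.03 and -0.04 at day 42, and none passed the test. In all, 1094 genes rose and 1791 fell at day 42, and 805 rose and 936 fell from day 3 to day 42. The day 42 count was 705 in J mice alone, 1580 in N mice alone and 1815 with marker scores of muscle and red blood cells as covariates, and the count of 1741 for day 42 against day 3 was then 315.

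**Figure D3:**
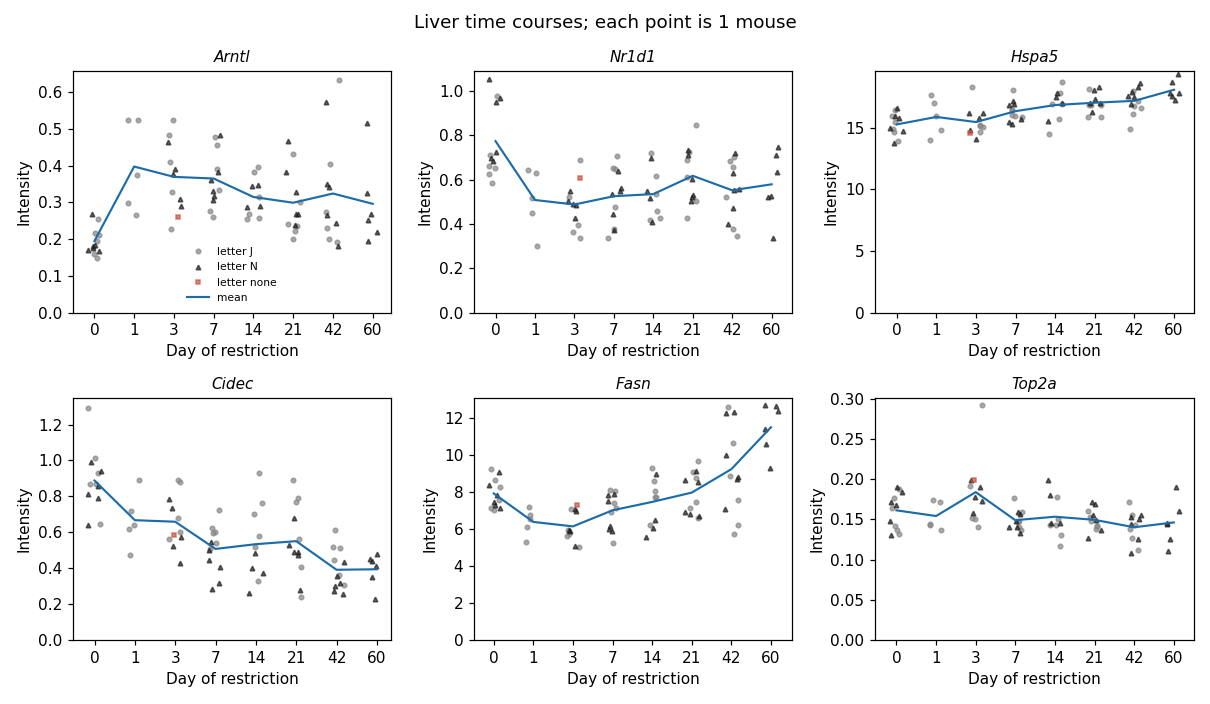
Intensity of 6 genes in liver by day of restriction, with a point per mouse and a line through the mean of each day. Arntl rises by 0.95 on the log2 scale at day 3, Nr1d1 is lower, and Cidec falls by 1.21 at day 42.

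In the depot labelled subcutaneous, Mest and Lep were among the genes that fell at day 42 (n = 11 against 12). Mest, which rises in growing fat, fell by 1.03 ± 0.14 (adjusted p = 1.43e-06, 11 of 11 mice), and Lep, the leptin gene, fell by 0.64 ± 0.16 (adjusted p = 0.0109, 10 of 11 mice). Of 17 adipose expansion and adipokine genes 10 fell and 0 rose, with 14 and 1 adjusted over the list alone (adjusted p = 0.145 with an estimated correlation). Of 25 extracellular matrix genes 18 fell and 0 rose, with 21 and 1 adjusted over the list alone (adjusted p = 0.145 with an estimated correlation). Col15a1 and Col1a1, collagen genes, fell by 0.65 ± 0.11 and 0.35 ± 0.07. Of 24 genes of fatty acid and triglyceride synthesis 5 rose and 0 fell, with 9 and 0 adjusted over the list alone (adjusted p = 0.361 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, rose by 0.26 ± 0.04, Acaca, acetyl-CoA carboxylase, by 0.43 ± 0.10 and the fatty acid elongase gene Elovl6 by 0.65 ± 0.17.

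Cholesterol genes in the depot labelled subcutaneous counted 5 of 18 higher and 0 lower, and 10 and 1 adjusted over the list alone (adjusted p = 0.361 with an estimated correlation), with Mvd up by 0.49 ± 0.09. The glycogen-targeting gene Ppp1r3b rose by 0.71 ± 0.17, the tubulin gene Tuba8 by 0.70 ± 0.16, Angptl8 by 0.62 ± 0.18, Nat8l by 0.60 ± 0.13, the cytokine-signalling inhibitor gene Cish by 0.57 ± 0.15 and the acetoacetyl-CoA synthetase gene Aacs by 0.52 ± 0.13. The eosinophil ribonuclease gene Rnase2a fell by 1.57 ± 0.27, Tph2, a serotonin synthesis gene, by 1.48 ± 0.20, Prr32 by 1.34 ± 0.24, Wfdc21 by 1.20 ± 0.17, the sodium pump gene Atp1a4 by 1.11 ± 0.17 and the phospholipase gene Pla2g2e by 0.94 ± 0.17. The chemokine gene Ccl2 fell by 0.51 ± 0.11. In all, 146 of 13443 genes rose and 396 fell at day 42, and 44 rose and 146 fell from day 3 to day 42. The day 42 count of 542 was 6 in J mice alone, 79 in N mice alone, 1333 with marker scores of other tissues as covariates and 166 without arrays high in them. The day 60 count of 1308 was 761 without the letter term and 865 without those arrays.

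In the depot labelled mesenteric, proliferation and matrix genes were lower at day 42 (n = 11 against 12). Of 23 cell cycle genes 22 fell and 0 rose, and also 22 adjusted over the list alone (adjusted p = 0.139 with an estimated correlation). Prc1 fell by 0.74 ± 0.07 (adjusted p = 7.29e-12) and Top2a, a DNA topoisomerase gene, by 0.70 ± 0.08, each in 11 of 11 mice. Of 25 matrix genes 21 fell and 2 rose, and also 21 and 2 adjusted over the list alone (adjusted p = 0.427 with an estimated correlation), with the metalloproteinase inhibitor gene Timp1 down by -0.79 ± 0.09 and Col1a1 by -0.36 ± 0.05. Of 19 macrophage genes 12 fell and 0 rose, and 12 adjusted over the list alone (adjusted p = 0.947 with an estimated correlation). Of 15 T and NK cell genes 4 fell and 0 rose, of 13 B cell genes 2 fell and 0 rose, and of 14 skeletal muscle genes 2 fell and 1 rose, the same counts as adjusted over the list alone (adjusted p = 0.95, 0.947 and 0.962 with an estimated correlation). Ccr2, the receptor of Ccl2, fell by 0.64 ± 0.10, and Itgam, an integrin gene of myeloid cells, by 0.57 ± 0.10. Ccl2 itself fell by 0.39 ± 0.09 and Lep by 0.20 ± 0.05. Of 18 cholesterol genes 2 rose and 9 fell, with 2 and 13 adjusted over the list alone (adjusted p = 0.947 with an estimated correlation), among them Dhcr7, down by -0.31 ± 0.05. Of 24 fatty acid and triglyceride synthesis genes 10 rose and 5 fell, the same counts as adjusted over the list alone (adjusted p = 0.947 with an estimated correlation).

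Single genes with the largest day 42 changes in the depot labelled mesenteric included Tph2 (-2.13 ± 0.24), Rnase2a (-1.76 ± 0.23), the serum amyloid gene Saa3 (-1.48 ± 0.14), S100a7l2 (-1.45 ± 0.18), the proteoglycan gene Ncan (-1.30 ± 0.16), the gastric lipase gene Lipf (-1.27 ± 0.17) and the calprotectin gene S100a8 (-1.23 ± 0.13), each in 11 of 11 mice. Higher were the kinase gene Ripk4 (0.99 ± 0.23), 9530026P05Rik (0.87 ± 0.11), Cish (0.75 ± 0.17), the sialyltransferase gene St6galnac5 (0.70 ± 0.10), the methyltransferase gene Inmt (0.69 ± 0.07), Tuba8 (0.67 ± 0.14) and the calcium-binding protein gene Hpca (0.67 ± 0.13). At day 3, Apol11b, the pantetheinase gene Vnn1, Ccn5 and Sptlc3 rose by 0.91 ± 0.18, 0.79 ± 0.10, 0.61 ± 0.13 and 0.61 ± 0.13, each in 10 of 10 mice. The cannabinoid receptor gene Cnr1, the deiodinase gene Dio2, Adamts16 and the histone gene H3c15 fell by 0.40 ± 0.08, 0.39 ± 0.09, 0.38 ± 0.10 and 0.33 ± 0.07. Of 18 cholesterol genes 2 fell at day 3, and 10 adjusted over the list alone (adjusted p = 0.0566 with an estimated correlation). In all, 42 of 13475 genes rose and 31 fell at day 3, 2024 rose and 2314 fell at day 42, and 1333 rose and 1833 fell from day 3 to day 42. The day 3 count of 73 was 3 in J mice alone, 5 in N mice alone, 280 with marker scores as covariates and 141 without arrays high in them, and the day 42 count was 899 in J mice alone.

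In the depot labelled perirenal, day 42 again brought lower matrix and cell cycle genes (n = 12 against 12). Of 25 matrix genes 21 fell and 0 rose, with 21 and 1 adjusted over the list alone (adjusted p = 0.438 with an estimated correlation). Col12a1 fell by 0.51 ± 0.08, Timp1 by 0.60 ± 0.11 and Col1a1 by 0.42 ± 0.09. Of 22 cell cycle genes 19 fell and 0 rose, with 21 lower adjusted over the list alone (adjusted p = 0.438 with an estimated correlation), and Prc1 fell by 0.61 ± 0.09 (adjusted p = 1.27e-06, 12 of 12 mice). Of 17 adipose expansion genes 8 fell and 1 rose, with 9 and 1 adjusted over the list alone (adjusted p = 0.84 with an estimated correlation), and Lep fell by 0.46 ± 0.12. Of 20 insulin and growth factor signalling genes 7 rose and 0 fell, and 7 adjusted over the list alone (adjusted p = 0.801 with an estimated correlation). These included Insr, the insulin receptor gene (0.11 ± 0.02), and Slc2a4, the insulin-responsive glucose transporter gene (0.16 ± 0.04). Ccl2 fell by 0.47 ± 0.11, and 4 of 18 macrophage genes fell, also 4 adjusted over the list alone (adjusted p = 0.942 with an estimated correlation). Ucp1 differed by -0.24 ± 0.51 (adjusted p = 0.791, 6 of 12 mice lower).

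The largest day 42 decreases in the depot labelled perirenal were those of Tph2 (-2.36 ± 0.26), Rnase2a (-1.92 ± 0.18), Saa3 (-1.45 ± 0.16), Atp1a4 (-1.34 ± 0.19), Lipf (-1.28 ± 0.20), the orphan receptor gene Gpr50 (-1.27 ± 0.25) and the kinase gene Cdkl4 (-1.05 ± 0.19). The largest increases were those of Cish (0.65 ± 0.19), St6galnac5 (0.61 ± 0.13), 9530026P05Rik (0.61 ± 0.08), the B cell chemokine gene Cxcl13 (0.58 ± 0.19), the follistatin gene Fst (0.55 ± 0.07), the actin-severing gene Scin (0.51 ± 0.10) and the glucose transporter gene Slc2a3 (0.50 ± 0.12). At day 3 Vnn1 rose by 0.57 ± 0.12 (adjusted p = 0.0314, 10 of 10 mice), and Rnase2a and Abcb9 fell by 1.00 ± 0.19 and 0.18 ± 0.04. In all, 1 of 13633 genes rose and 2 fell at day 3, 1715 rose and 1280 fell at day 42, and 1583 rose and 1256 fell from day 3 to day 42. The day 3 count of 3 was 0 in J mice alone, 0 in N mice alone, 0 without arrays high in marker scores of other tissues and 25 with those scores as covariates. The day 42 count was 1525 in J mice alone, 445 in N mice alone and 1941 without those arrays.

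In the depot labelled perigonadal, 6 of 22 cell cycle genes fell and 0 rose at day 3 (n = 11 against 11), with 19 lower adjusted over the list alone (adjusted p = 0.136 with an estimated correlation). The mitotic genes Pbk, Cenpf, Aspm and Prc1 fell by 0.63 ± 0.11, 0.58 ± 0.11, 0.51 ± 0.12 and 0.48 ± 0.09, and Prc1 did so in 9 of 10 mice (adjusted p = 0.000717). Of 18 macrophage genes 4 rose and 0 fell, with 12 higher adjusted over the list alone (adjusted p = 0.136 with an estimated correlation), among them Fcgr1, an immunoglobulin receptor gene (0.35 ± 0.07), and Cd68 (0.33 ± 0.08). The 3 erythrocyte markers Alas2, Slc4a1 and Car2 rose by 0.52 ± 0.09, 0.41 ± 0.08 and 0.26 ± 0.04, and all 3 rose adjusted over the list alone (adjusted p = 5.9e-05 with an estimated correlation). Apol11b, Ccn5 and the mast cell chymase gene Cma1 rose by 0.88 ± 0.17, 0.64 ± 0.13 and 0.57 ± 0.14.

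At day 42 in the depot labelled perigonadal (n = 10 against 11), 21 of 22 cell cycle genes fell and 0 rose, and also 21 adjusted over the list alone (adjusted p = 0.0642 with an estimated correlation). The kinetochore gene Spc25 fell by 1.21 ± 0.12 and the proliferation marker Mki67 by 1.19 ± 0.14, each in 10 of 10 mice. Of 25 matrix genes 16 fell and 3 rose, with 17 and 3 adjusted over the list alone (adjusted p = 0.408 with an estimated correlation), and Col15a1 fell by 0.56 ± 0.05. Of 22 fatty acid oxidation genes 11 fell and 2 rose, with 12 and 3 adjusted over the list alone (adjusted p = 0.547 with an estimated correlation), among them the dehydrogenase gene Acadm, down by -0.14 ± 0.02. Rnase2a, Tph2, Saa3, Lipf and Pla2g2e fell by 2.25 ± 0.24, 2.08 ± 0.22, 1.74 ± 0.22, 1.60 ± 0.19 and 1.29 ± 0.14. Cxcl13 rose by 1.15 ± 0.28, the neutrophil protease gene Prtn3 by 0.89 ± 0.14, Tuba8 by 0.83 ± 0.25, Bex1 by 0.82 ± 0.28, Cish by 0.78 ± 0.21, the angiotensinogen gene Agt by 0.71 ± 0.13 and Myoc by 0.70 ± 0.18. Lep fell by 0.13 ± 0.03, and Ccl2 differed by -0.22 ± 0.12 (adjusted p = 0.163, 9 of 10 mice lower). In all, 109 of 13450 genes rose and 98 fell at day 3, 1782 rose and 1833 fell at day 42, and 1456 rose and 1542 fell from day 3 to day 42. The day 3 count of 207 was 15 in N mice alone, 328 with marker scores of other tissues as covariates and 15 without arrays high in them, and the day 42 count was 1149 in J mice alone, 2222 in N mice alone and 1809 with the scores. With the scores the count of 2998 from day 3 to day 42 was 1147.

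**Figure D4:**
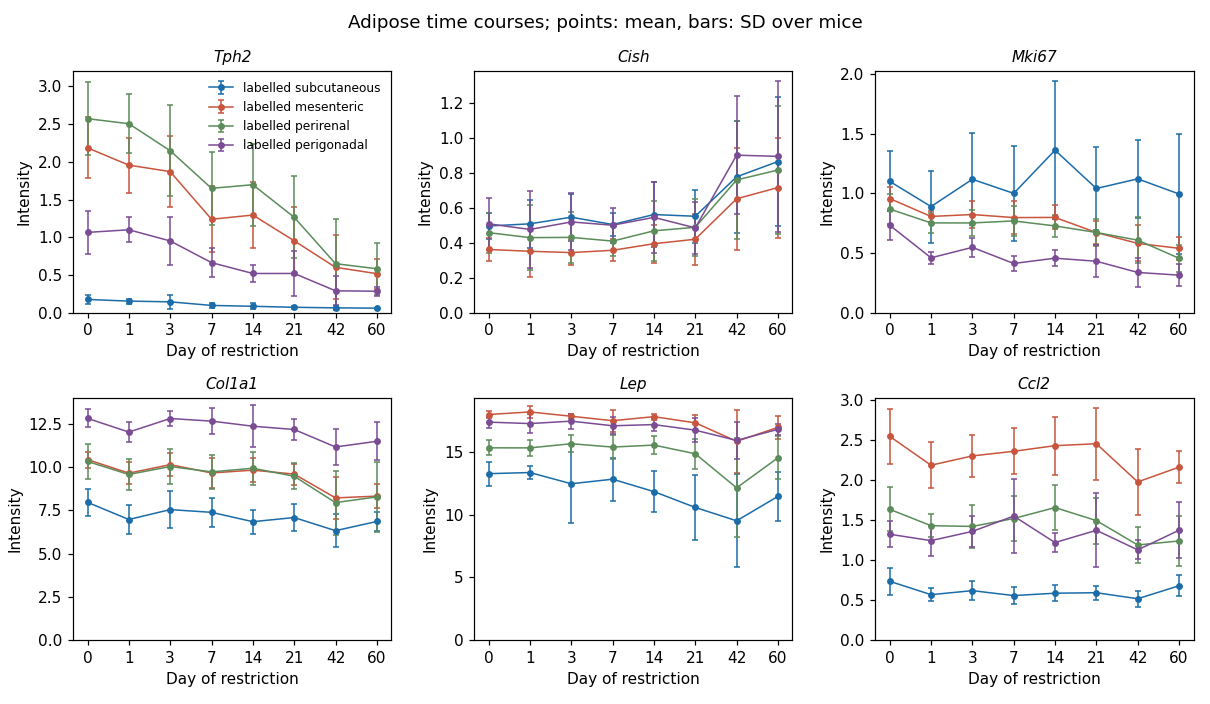
Intensity of 6 genes by day of restriction in the 4 depots as labelled, as mean ± SD over the mice of a day. Tph2 and Col1a1 fall with time in each depot, and at day 42 the log2 change of Tph2 lies between -2.36 and -1.48.

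Across the depots, 219 of the 12729 genes tested in all 4 changed the same way at day 42, 34 higher and 185 lower. Independent lists of the same sizes would share 0.418 higher and 0.958 lower genes, and the depots come from the same mice, so the lists are not independent. The mean change over the 4 depots was -2.01 for Tph2, -1.87 for Rnase2a, -1.22 for Lipf and 0.69 for Cish. Fst, which encodes an activin-binding protein, and Acaca had means of 0.53 and 0.30. Erythrocyte markers were higher at day 3 as a set in the depots labelled subcutaneous (3 genes, 0 called, and 2 adjusted over the list alone, adjusted p = 0.00044 with an estimated correlation) and mesenteric (2 called, and 2 adjusted over the list alone, adjusted p = 0.00347). Of the 3 markers 0 were called by limma in the depot labelled perirenal, and 2 adjusted over the list alone (adjusted p = 0.266).

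A difference in the size of the day 42 change between depots was called for a minority of genes. In simulation a shift of 0.25 was recovered for 40.3% to 42.4% of genes in these comparisons, so smaller differences can be missed. Against the depot labelled subcutaneous, Mki67 changed by -1.21 ± 0.26 more in that labelled perigonadal (adjusted p = 0.00936), where its own change was -1.19 against 0.01. B cell markers had a median log2 level of 0.26 in the depot labelled subcutaneous. Their levels in those labelled mesenteric, perirenal and perigonadal were -2.11, -1.85 and -2.28. What such cells add to the differences in cell cycle genes was not tested. Saa3 differed by -0.97 ± 0.24 in the depot labelled mesenteric and by -1.23 ± 0.30 in that labelled perigonadal. Prtn3 differed by 0.97 ± 0.19 in the depot labelled perigonadal, and Prr32 by 1.02 ± 0.28 in that labelled mesenteric. In that depot 12 of 23 cell cycle genes and 8 of 18 cholesterol genes had a lower change than in the depot labelled subcutaneous, and 0 of each a higher one. The median difference there was -0.61 for the cell cycle list, -0.67 for markers of intestine and lymphatic tissue and -0.49 for those of exocrine pancreas, and no single marker of the latter lists passed the test. In the depot labelled perigonadal 5 of 23 cell cycle genes had a lower change and 0 a higher one. The median difference in that depot was -0.62 for the cell cycle list and 1.05 for skeletal muscle markers. It was -0.72 for markers of intestine and lymphatic tissue and -0.53 for those of exocrine pancreas, with 0 of these markers called. The tests called 371 genes for the depot labelled mesenteric (178 higher, 193 lower), 5 for that labelled perirenal and 85 for that labelled perigonadal (29 higher, 56 lower). The 5 genes, named after their values were seen, were Ankrd29, Ivns1abp, Rassf3, Rnf146 and Acoxl. With the animal as a block, within-animal differences gave 766, 26 and 243 genes. Without arrays high in marker scores of other tissues the counts were 9, 1 and 8. That omission left out 18 of 78 arrays labelled subcutaneous, 30 of 79 labelled mesenteric, 43 of 80 labelled perirenal and 29 of 75 labelled perigonadal. With the scores as covariates the first 2 counts were 739 and 58.

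Between animals of letter N and letter J, genes with large differences included markers of neighbouring tissue in hypothalamus and in the depot labelled mesenteric. In hypothalamus (36 N and 37 J arrays), Crym, Gabrd and Ppp1r1b, which are abundant in cortex and striatum, were lower in N by -0.71 ± 0.17, -0.70 ± 0.12 and -0.61 ± 0.14. Npvf, a hypothalamic neuropeptide gene, was higher by 0.50 ± 0.16. The mean score of thalamus, cortex and striatum markers was lower in N by -0.14 ± 0.03, with 5 of 12 lower over all genes and 6 adjusted over the list alone (adjusted p = 0.387 with an estimated correlation). Among genes of the depot labelled mesenteric, the liver genes Ttr and Alb were higher in N by 2.33 ± 0.22 and 1.36 ± 0.18, and the epididymal gene Crisp1 was lower by -1.59 ± 0.40. Of 11 hepatocyte genes 9 were higher there, and of 11 testis and epididymis genes 9 were lower, the same counts as adjusted over the list alone (adjusted p = 0.449 and 0.677 with an estimated correlation). In liver the asparagine synthetase gene Asns, Cidea and Cidec were lower in N by -0.64 ± 0.11, -0.59 ± 0.13 and -0.39 ± 0.09. These genes were chosen for their large differences after the values were seen.

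The letter separated 2502 genes in hypothalamus (1449 higher in N, 1053 lower), 2004 in liver (1342 and 662), 1121 in the depot labelled subcutaneous (692 and 429), 4059 in that labelled mesenteric (2360 and 1699), 8 in that labelled perirenal and 315 in that labelled perigonadal (101 and 214). With marker scores of other tissues as covariates the counts were 0 in hypothalamus, 0 in the depot labelled subcutaneous, 199 in that labelled mesenteric and 3 in that labelled perirenal. Without arrays high in these scores they were 0, 507, 0 and 52 in the depots labelled subcutaneous, mesenteric, perirenal and perigonadal. Whether the day 42 change of Cidec, Tph2 or any other gene differed between the letters was tested in each tissue, and limma called 0 genes in all 6. At an unadjusted p under 0.05 it gave 253 in hypothalamus, 617 in liver, and 184, 564, 766 and 996 in the depots labelled subcutaneous, mesenteric, perirenal and perigonadal. The count in the depot labelled mesenteric was 425 without arrays high in the marker scores and 2 with the scores as covariates.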

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

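Written beforehand were the test of Nnt and the comparisons with other splits. The tests of the depot names, of the clock genes, of the marker scores and of Arntl by letter were chosen only after the result was seen.

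In 7 of 33 pairs of a named gene and a group of 4 to 10 arrays, 1 array lay far from the others. The bound used has a nominal rate of about 1 in 20 by chance, which was not checked here. The 7 pairs come from 2 groups of arrays, so they are not independent and were not set against chance. In hypothalamus at day 0 (n = 10) the value apart was that of Hcrt at 2.84 (nearest 6.31), Pmch at 15.4 (nearest 20.2) and Crh at 1.42 (nearest 1.65). At day 42 in the depot labelled perigonadal (n = 10) it was that of Scd1 at 18.7 (20.1), Ucp1 at 0.316 (0.207), Trem2 at 0.714 (0.516) and Col1a1 at 8.54 (10.4).

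The day 42 change differed from that in the depot labelled subcutaneous for 371 genes in that labelled mesenteric, 5 in that labelled perirenal and 85 in that labelled perigonadal. The differences in the depot labelled mesenteric were 0.66 for 9530026P05Rik, 0.10 for Adipoq, 0.44 for Inmt, 1.02 for Prr32, -0.81 for S100a8, -0.97 for Saa3 and 0.77 for St6galnac5. Those in the depot labelled perigonadal were -0.89 for Lipf, -1.21 for Mki67, 0.97 for Prtn3, -1.23 for Saa3, -1.02 for Spc25 and 0.73 for Wfdc21. Probe sets without a gene name also changed at day 42, 460 in liver and 20, 740, 425 and 316 in the depots labelled subcutaneous, mesenteric, perirenal and perigonadal.

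Marker genes of 3 depots did not go with their labels, and in 98.6% of the animals with all 3 arrays (72 of 73), exocrine pancreas markers were highest in the array labelled subcutaneous, testis and epididymis markers highest in that labelled mesenteric and Wt1 lowest in that labelled perigonadal, so a candidate explanation is that the 3 names were exchanged in a cycle. These checks restate the observation that prompted them, and Tbx15, also chosen after its values were seen, was at 0.434 or more in every array labelled perigonadal, against at most 0.152, 0.0656 and 0.329 in those labelled subcutaneous, mesenteric and perirenal. Single arrays exchanged with the depot labelled perigonadal are argued against, since 100% of the arrays labelled perigonadal had Wt1 below every array labelled perirenal. Wt1 overlapped between the arrays labelled subcutaneous (0.206 to 1.20), mesenteric (0.275 to 0.828) and perirenal (0.0785 to 0.429). It therefore cannot show single exchanges among these depots. Mesothelial genes diluted by other tissue at dissection are argued against by Adipoq, whose median in the arrays labelled perigonadal was 1.01 times that in those labelled perirenal, with Wt1 at 0.0791 times. The median of Wt1 in the arrays labelled perigonadal (0.0202) lay near that in hypothalamus (0.0189), so its ratio may be set by background. The Adipoq test replaced one of the median of Wt1 over the lowest perirenal value, which came out at 0.257 and missed its bound of 0.25. No biological explanation was tested.

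Many genes differed between animals of letter N and letter J. Substrains that differ in Nnt are argued against, since its largest absolute difference over the 6 tissues was 0.0461. That difference, in liver, was small but called by limma (adjusted p = 0.0149), and the position of the probe set in the gene was not examined. Another time of day is argued against by the liver clock genes, whose median absolute difference was 0.0240. In hypothalamus 0% of the genes stayed called with marker scores of neighbouring brain as covariates, and the median absolute difference went from 0.0670 to 0.0281 while the standard error went from 0.0196 to 0.0214, so another share of neighbouring brain may contribute. For the depot labelled mesenteric 4.56% stayed called, so another share of neighbouring tissue may contribute there, and in liver 96.9% stayed called, which argues against muscle or blood RNA. In the depots labelled subcutaneous, perirenal and perigonadal 0%, 25% and 60.6% stayed called, without a test set up for them. The median absolute difference of the called genes went from 0.150 to 0.0824, from 0.0960 to 0.102 and from 0.0740 to 0.0704 in the same order. In that labelled mesenteric it went from 0.0936 to 0.0537. A difference between the animals that the letter stands for stays open as untested.

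Clock genes in liver had moved at day 3. For Arntl one letter alone is argued against, since the smaller of its changes in J and N mice was 0.93. The other clock genes were not tested by letter in this way. Another time of day at sampling was taken to move the clock genes the same way in every tissue of the same mice. A tissue whose clock genes moved another way would not meet this, so the test holds only under that reading. The 10 clock genes called in liver had a median of 0.41 there in the direction of their change, and medians of 0.02 in hypothalamus and 0.05, -0.02, 0.00 and 0.09 in the depots labelled subcutaneous, mesenteric, perirenal and perigonadal, with median absolute deviations of 0.04, 0.10, 0.11, 0.08 and 0.18, which argues against it as the whole cause. The largest share of the change in liver reached elsewhere was 0.215, under the bound of 0.25 as first written, which was tightened by a standard error after the value was seen and then restored, and with that margin (0.07) the depot labelled perigonadal would not have met it. A smaller part from sampling time there, and a shift of the clock at day 3 mainly in liver, by restriction or by the hour of feeding, stay open as untested. Of the 10 genes, 7 went in the direction of liver in hypothalamus. In the depots labelled subcutaneous, mesenteric, perirenal and perigonadal 7, 4, 5 and 8 did. The clock list as a set also lay lower in hypothalamus at day 3, as given above. At day 42 the same 10 genes had medians in that direction of 0.18 in liver and 0.15 in the depot labelled subcutaneous. Those in hypothalamus and in the depots labelled mesenteric, perirenal and perigonadal were -0.00038, -0.07, -0.02 and -0.03.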

How the results depend on the processing

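The marker scores of other tissues as covariates and the omission of arrays high in them were added after the data were seen. Quantile normalization moved 0 of 69 counts by over 1.5 times. The depots are named as labelled.

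With J mice alone, the day 3 counts were 1 in liver, 3 in mesenteric and 0 in perirenal, and those of day 42 were 705 in liver, 899 in mesenteric, 1149 in perigonadal, 1525 in perirenal and 6 in subcutaneous. With N mice alone, those of day 3 were 76 in liver, 5 in mesenteric, 15 in perigonadal and 0 in perirenal, and those of day 42 were 1580 in liver, 2222 in perigonadal, 445 in perirenal and 79 in subcutaneous. These settings hold fewer mice. Acly at day 42 in mesenteric was -0.0096 with J mice alone, of the opposite sign, with an adjusted p of 0.949.

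With the median over probe sets the counts were 53 in perirenal at day 14, 1 in hypothalamus at day 60 and 56 in perirenal for the letter. Without the letter term they were 2 in perirenal at day 1, 1 in hypothalamus and 1 in perirenal at day 3, 1 in hypothalamus and 761 in subcutaneous at day 60, and 115 in subcutaneous from day 3 to day 42. With no filter on low values they were 1 in hypothalamus and 18 in perirenal at day 1, and 191 in subcutaneous for the letter. The cause was not tested.

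With marker scores as covariates the counts were 104 in perigonadal at day 1; at day 3, 280 in mesenteric, 328 in perigonadal and 25 in perirenal; at day 7, 85 in mesenteric, 66 in perirenal and 117 in subcutaneous; at day 14, 323 in mesenteric, 32 in perirenal and 56 in subcutaneous. At day 21 they were 733 in mesenteric and 115 in subcutaneous, at day 42 1815 in liver, 1809 in perigonadal and 1333 in subcutaneous, and at day 60 38 in hypothalamus, 1945 in mesenteric and 1579 in perigonadal. From day 3 to day 42 they were 315 in liver, 1147 in perigonadal and 696 in subcutaneous, and on any day 1 in hypothalamus, 2538 in perigonadal and 1466 in subcutaneous. For the letter they were 0 in hypothalamus, 199 in mesenteric, 3 in perirenal and 0 in subcutaneous, for the letter by day 42 interaction 2 in mesenteric, and for the difference from subcutaneous 739 in mesenteric and 58 in perirenal. The cause was not tested.

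Without arrays high in the scores the counts at day 1 were 0 in mesenteric, 13 in perigonadal, 3 in perirenal and 3 in subcutaneous; at day 3, 141 in mesenteric, 15 in perigonadal and 0 in perirenal; at day 7, 60 in mesenteric, 284 in perigonadal and 0 in perirenal; at day 14, 928 in liver, 239 in mesenteric, 5 in perirenal and 2 in subcutaneous. At day 21 they were 1589 in perigonadal, 228 in perirenal and 0 in subcutaneous, at day 42 2 in hypothalamus, 1941 in perirenal and 166 in subcutaneous, and at day 60 1 in hypothalamus and 865 in subcutaneous. From day 3 to day 42 the count was 1548 in perirenal, and on any day 1489 in perirenal and 309 in subcutaneous. For the letter they were 507 in mesenteric, 52 in perigonadal, 0 in perirenal and 0 in subcutaneous, for the interaction 425 in mesenteric, and for the difference from subcutaneous 9 in mesenteric, 8 in perigonadal and 1 in perirenal. This setting left out 2 of 74 arrays in hypothalamus, 7 of 80 in liver, 18 of 78 in subcutaneous and 30 of 79 in mesenteric. It left out 43 of 80 in perirenal and 29 of 75 in perigonadal. Counts can fall for that reason alone, and the cause of the higher counts was not tested.

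With the animal as a block, the paired differences from subcutaneous gave 766 genes in mesenteric, 26 in perirenal and 243 in perigonadal. No other result was fitted with the block. Leaving out each day 1 mouse gave 0 to 5 genes in hypothalamus (5 without J7), 140 to 703 in liver (271 without J15, 180 without J20, 140 without J60), 0 to 1 in subcutaneous (1 without J7, 1 without J20, 1 without J60), 2 to 6 in mesenteric (2 without J15, 3 without J20, 2 without J60), 0 to 58 in perirenal (0 without J7, 8 without J15, 58 without J20, 13 without J60, 18 without J80) and 3 to 83 in perigonadal (30 without J7, 14 without J15, 22 without J20, 3 without J60, 83 without J80). Of the list results, 94 of 338 lost their call with the estimated correlation, 32 with marker scores as covariates, 23 without arrays high in them, 9 without the letter term and 6 with quantile normalization, and 0, 17, 22, 7 and 7 gained one. Of the calls of named genes, 64 were lost in J mice alone, 47 in N mice alone, 24 without arrays high in the scores, 13 with the scores as covariates, 4 with quantile normalization, 3 with the median over probe sets and 2 without the letter term, and 1, 0, 2, 3, 6, 4 and 0 were gained.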

Other observations

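Every comparison of counts with 100 splits of the same animals was written beforehand, and the real split is included in each number of splits below. The bound written beforehand was a share under 0.05 of the splits. Where this bound was met but another split gave as many genes, chance is left open below. These numbers were not adjusted for the many comparisons made. Some splits called many genes, several times the real count, and the reason was not tested.

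In liver 1 of 100 splits, the real one, gave as many genes for each day count and for the letter, which argues against chance. The real and the highest other counts were 3856 and 1 on any day, 492 and 88 at day 1, 553 and 33 at day 3, 1139 and 2 at day 7, 1652 and 11 at day 14, 1211 and 4 at day 21, 2885 and 2 at day 42, 2711 and 1 at day 60, 1741 and 1 from day 3 to day 42 and 2004 and 4 for the letter. For the depot labelled perigonadal it was also 1 of 100 for each, with 4853 and 422, 48 and 3, 207 and 16, 1284 and 290, 1804 and 20, 2634 and 1244, 3615 and 767, 2925 and 2131, 2998 and 160, and 315 and 11 in the same order.

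Among the splits for the depot labelled mesenteric, 1 of 100 gave as many genes on any day (5143, highest other 1189), at day 7 (517, 0) and day 14 (587, 56). It was also 1 at day 21 (2229, 8), day 42 (4338, 251) and day 60 (3524, 17), from day 3 to day 42 (3166, 2018) and for the letter (4059, 410). Chance is argued against for these comparisons. At day 3 it was 3 splits (73, 878), which met the bound, and at day 1 it was 8 (6, 3861), which did not. Other splits gave more genes at these days, so chance cannot be excluded there. For the depot labelled perirenal 1 of 100 gave as many genes on any day (3395, 8), at day 14 (80, 2), day 21 (458, 220) and day 42 (2995, 2). It was also 1 at day 60 (2744, 69), from day 3 to day 42 (2839, 106) and for the letter (8, 2). It was 2 at day 3 (3, 548), 3 at day 7 (13, 698) and 7 at day 1 (5, 112), so chance cannot be excluded at these days.

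For the depot labelled subcutaneous 1 of 100 splits gave as many genes at day 42 (542, highest other 14) and day 60 (1308, 822), which argues against chance there. It was 2 on any day (778, 1766), from day 3 to day 42 (190, 192) and for the letter (1121, 3622). It was 3 at day 14 (9, 620) and 4 at day 21 (21, 4199). Other splits gave more genes in these last comparisons, so chance cannot be excluded for them. In hypothalamus 1 of 100 gave as many genes for the letter (2502, 134). It was 2 at day 60 (2, 361), 3 on any day (2, 41) and 5 from day 3 to day 42 (1, 1129), so chance cannot be excluded for these 3.

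Where limma called 0 genes, 100 of 100 splits gave as many by necessity, so the splits say nothing about these comparisons. The highest counts called in the other splits were 3773 at day 1, 2064 at day 3 and 20 at day 7 in the depot labelled subcutaneous, and 80, 373, 0, 665, 0 and 0 at days 1, 3, 7, 14, 21 and 42 in hypothalamus. For the letter by day 42 interaction they were 1 in hypothalamus, 7 in liver, and 1656, 206, 2127 and 47 in the depots labelled subcutaneous, mesenteric, perirenal and perigonadal.

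At an unadjusted p under 0.05, a threshold not used for the splits, the real groups of these comparisons gave 348, 283 and 391 genes at days 1, 3 and 7 in the depot labelled subcutaneous. In hypothalamus they gave 1345, 1103, 435, 234, 1405 and 733 at days 1, 3, 7, 14, 21 and 42, where limma called 0. For the interaction they gave 253 in hypothalamus, 617 in liver, and 184, 564, 766 and 996 in the depots labelled subcutaneous, mesenteric, perirenal and perigonadal.

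For the difference from the depot labelled subcutaneous 1 of 100 did in that labelled mesenteric (371, 110), perirenal (5, 0) and perigonadal (85, 0). For the genes changed the same way in 4 depots 1 of 100 did (219, 0). This argues against chance, except for the 5 genes in the depot labelled perirenal. There chance stays open, since the simulated data gave 12 false calls in the same comparison.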
